A study of Homo sapiens with 6 samples.

How the data were processed

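RNA was sequenced from 6 libraries of U2OS osteosarcoma cells, 3 given a scrambled siRNA (siSCR) and 3 given an siRNA against SURF2 (siSURF2). Per the labels' protocols, cells grew in medium with 10% serum at 37 °C and 5% CO2, siRNAs were given in 2 transfections 49 h apart and cells were taken at 96 h. Per the same protocols, RNA was extracted with Trizol, and 2 µg of total RNA went into polyA libraries made by a commercial provider. The authors deposited raw read counts per gene in 1 table, without normalization. Per the submitters' processing notes, the genome build was GRCh38 and the tools named include fastp 0.23.1 and STAR 2.5.2b. The counting tool, annotation version and strand setting are not given in the sources used here. Reads shared by paralogs, pseudogenes or overlapping genes on opposite strands can therefore have been split or dropped in a way that cannot be checked.

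The table held 58051 Ensembl gene identifiers and 92 ERCC spike-in sequences. Gene symbols came from a table of gene names for 56948 identifiers and from GENCODE release 29 for 499 more, and 604 stayed unnamed. Coordinates are those of GENCODE release 29 on GRCh38. Each of the 6 count columns was matched to a sample by its name. Spike-in rows were kept out of library sizes and tests, and held 1.12% to 1.72% of all counts in a library. Counts assigned to genes were 17123333, 18858476 and 19573786 in siSCR replicates 1, 2 and 3 and 18151554, 19310446 and 19688089 in siSURF2 replicates 1, 2 and 3. At these depths 1 CPM is about 17 to 20 counts, so levels well under 1 CPM rest on few counts.

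Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 17561 genes. Counts were normalised with TMM factors and tested with edgeR's quasi-likelihood F-test (robust dispersion, 1 term for the group), run in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change fitted without edgeR's prior count, divided by the square root of F. The log2 fold changes printed include that prior count, which matters for genes with few counts. CPM values are TMM-normalised and given as mean ± SD over 3 libraries. The common biological coefficient of variation was 5.13%.

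There were 27 gene lists, drawn up from general knowledge before the data were examined and covering the p53 pathway, cell cycle, ribosome, stress, immune, matrix and metabolic genes, markers of other cell types and of RNA quality. Lists were tested with camera of limma 3.58.1 (two-sided, preset inter-gene correlation 0.01, lists with at least 3 tested members), adjusted over the 27 lists. With an estimated correlation, 0 of the 27 lists passed (smallest adjusted p = 0.20), against 10 with the preset one. The lysosome and autophagy list had an estimate of 0.0050, below the preset 0.01, yet its unadjusted camera p rose from 7.3e-04 to 0.022. The 2 settings therefore differ in more than the size of the correlation, and a call lost with the estimate does not by itself show correlated members. The fry rotation test called 19 lists directionally and 26 in its mixed form, which do not compare a list with other genes.

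The genes named were set by a rule fixed before the data were examined. It takes SURF2, 11 genes of the p53 pathway and the surfeit cluster, the 8 highest and 8 lowest log2 fold changes among protein-coding genes past the threshold with a mean log2 CPM of at least 1 and non-overlapping groups, and, of each list, up to 2 members per direction with the smallest adjusted p, or 1 where none passed. Some genes that the rule takes are not reported here.

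Alternatives planned beforehand were RLE, upper-quartile and no normalization factors, no filter and a filter of 1 CPM in every library of a group, DESeq2 1.42.0, limma-voom, a non-robust dispersion prior, the replicate number as a block, thinning to the smallest library, leaving out each library, and other list tests. Scaling by ERCC totals, leaving out both libraries numbered 3, and lists without SURF2 or without genes holding certain 7-mers were added after seeing the data. DESeq2 and limma-voom were not used for lists.

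For the search of 7-mers in 3′ UTRs, log2 fold changes of protein-coding genes were limited to 2 in either direction and adjusted for UTR length, GC content and expression. Genes holding a 7-mer were compared with the rest for each 7-mer found in at least 50 genes, and 94.2% of protein-coding genes tested could be searched. Permutations shuffled the adjusted values over genes 100 times. Matched lists drew, for each list member, 1 of the 100 genes nearest in expression, exon length and GC content.

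The programs were tested on simulated data. For siSURF2 against siSCR with 17044 simulated genes and 200 true changes, the edgeR test recovered 48%, 78%, 92% and 100% of genes changed 1.3-, 1.5-, 2- and 4-fold, with 12 false calls. Far more genes were called in the data (9131 of 17561), so these rates need not hold there. In simulated lists, camera called a shifted list and 0 of 99 unshifted ones. Simulated genes varied independently, so this did not test camera on lists of correlated genes. In the 7-mer search, a planted 7-mer was recovered as the lowest. Its shift was larger than those of the 2 lowest 7-mers in the data (log2 -0.067 and -0.072), so recovery of shifts that small was not tested. Of 100 random lists, 3 passed the matched-list test at 0.05. Search and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.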

Results

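Gene expression was measured by polyA RNA sequencing in U2OS cells, a human osteosarcoma line. Cells received either a scrambled control siRNA (siSCR, 3 libraries) or an siRNA against SURF2 (siSURF2, 3 libraries). There were 2 transfections at a 49 h interval, and RNA was taken at 96 h. The title of the series names SURF2 as an antagonist of MDM2 in the nucleolar stress response, in which unassembled ribosomal proteins bind MDM2 and p53 accumulates. The comparison of siSURF2 with siSCR asked which mRNAs differed when SURF2 was lowered. Counts assigned to genes ranged from 17123333 in siSCR replicate 1 to 19688089 in siSURF2 replicate 3, and 27954 to 29293 genes had at least 1 count per library. The first principal component held 87.1% of the variance and separated the groups. Pairs of libraries of 1 group correlated at 0.996 to 0.997 across genes (Pearson, log2 CPM), and pairs across groups at 0.977 to 0.980. No pair of libraries agreed within sampling noise, the closest being siSCR replicates 1 and 2 with a chi-square of 2.53 per degree of freedom. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

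SURF2 (ENSG00000148291), on chromosome 9 at 133356552 to 133361169 (GRCh38), was lower in all siSURF2 libraries. Its level was 36.2, 35.8 and 32.3 CPM in siSCR replicates 1, 2 and 3 and 3.74, 3.56 and 3.20 CPM in siSURF2 replicates 1, 2 and 3. The means were 34.8 ± 2.11 CPM and 3.50 ± 0.276 CPM (SD, n = 3 each), a 9.93-fold lower level. The log2 fold change was -3.31 ± 0.10 (SE), with an edgeR adjusted p of 3.7e-20. The other genes of the surfeit cluster, a tight group of housekeeping genes around SURF2, did not all behave alike. SURF4, a cargo receptor of the endoplasmic reticulum, fell from 317.5 ± 7.50 to 242.0 ± 14.8 CPM (log2 fold change -0.39 ± 0.05, adjusted p = 1.9e-07). SURF6, a nucleolar protein of ribosome assembly, fell by 0.38 ± 0.06 on the log2 scale (adjusted p = 1.4e-05). SURF1, MED22 and RPL7A had log2 fold changes of -0.10, -0.02 and -0.04 and did not pass the threshold. The 5′ ends of SURF1 and SURF2 overlap on opposite strands, and the strand setting of the counts is not given in the sources used here. Reads from that stretch can therefore not be assigned with certainty. As a list, the 6 surfeit genes were called lower (camera adjusted p = 0.0020), but with an estimated correlation the adjusted p was 0.32. Without SURF2 itself, a choice made after seeing the data, the list had an adjusted p of 0.32.

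**Figure D1:**
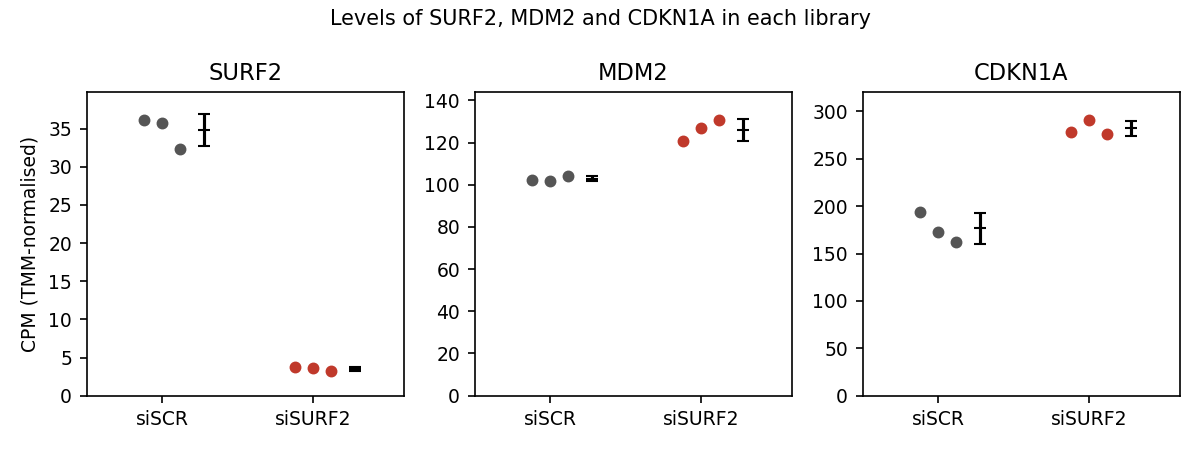
Levels of SURF2, MDM2 and CDKN1A in CPM (TMM-normalised, linear axis from 0), with 1 point per library and the mean ± SD of 3 libraries beside the points of each group. SURF2 lies at 32.3 to 36.2 CPM in siSCR and at 3.20 to 3.74 CPM in siSURF2, and the siSURF2 points of the other genes lie above all siSCR points.

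**Figure D2:**
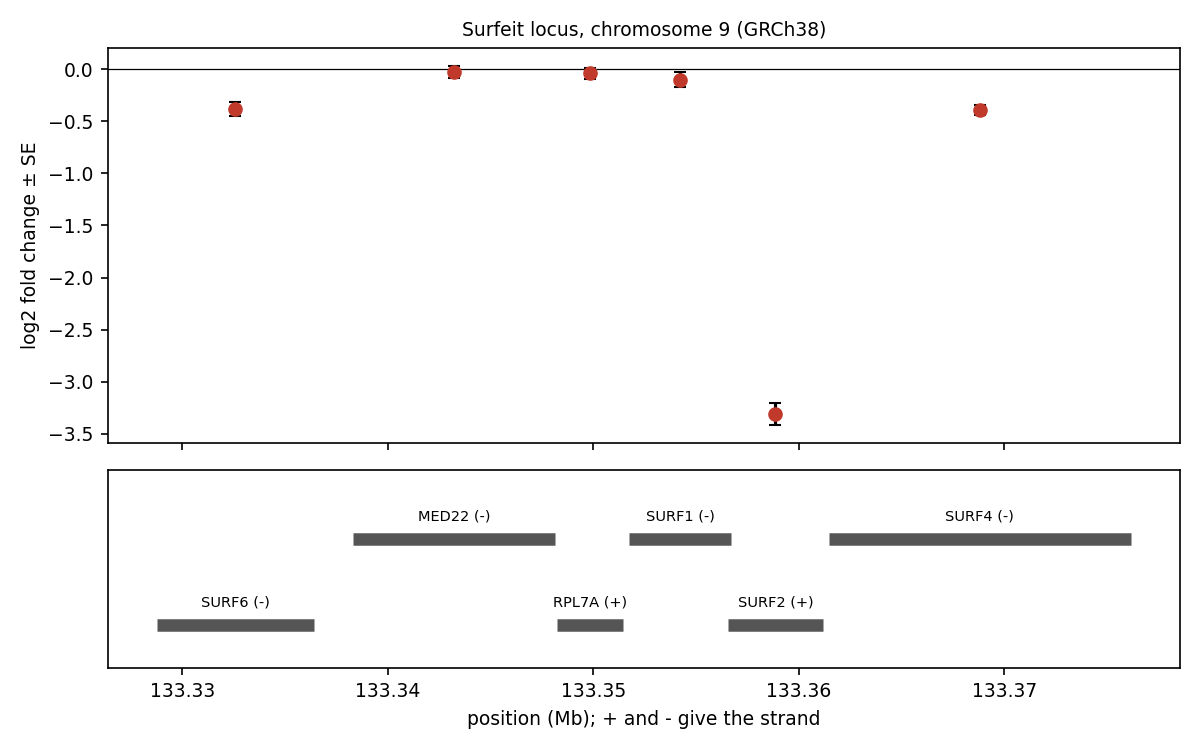
Log2 fold change ± SE (siSURF2 against siSCR, 3 libraries each) of the 6 surfeit genes at their midpoints on chromosome 9 (Mb, GRCh38), with the extent and strand of each gene below. SURF2 lies at -3.31, SURF4 at -0.39 and SURF6 at -0.38, and the other genes lie within 0.10 of 0.

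Single genes of the p53 pathway went both ways with siSURF2. CDKN1A, the cell cycle inhibitor p21, rose from 176.7 ± 16.2 to 282.0 ± 8.16 CPM (SD, n = 3 each), with a log2 fold change of 0.68 ± 0.06 (SE, edgeR adjusted p = 5.4e-11). MDM2, the ubiquitin ligase that degrades p53 and is itself a p53 target, rose by a log2 fold change of 0.30 ± 0.05 (adjusted p = 2.0e-05). RPL5 and RPL11, the ribosomal proteins that bind MDM2 together with 5S rRNA, had log2 fold changes of -0.07 ± 0.05 and -0.01 ± 0.05 and did not pass the threshold. NOP53, a nucleolar protein that carries this complex, rose by 0.26 ± 0.05. Of 12 measured members of a list of 5S ribonucleoprotein and MDM2-p53 core genes, 4 rose, 3 fell and 5 did not pass the threshold. SURF2, the siRNA target itself, was among those that fell (-3.31 ± 0.10), as was RRS1, an assembly factor of the 5S complex (-0.49 ± 0.06). That list was not called (camera adjusted p = 0.53), nor was it without SURF2, a choice made after seeing the data (camera adjusted p = 0.54).

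Of 51 measured p53 target genes, 37 rose, 6 fell and 8 did not pass the threshold over all genes tested (38 and 6 when adjusted over the list alone). The median log2 fold change was 0.35. GDF15, a secreted stress cytokine, rose from 4.33 ± 0.736 to 19.6 ± 0.568 CPM (log2 fold change 2.19 ± 0.12), and E2F7, a repressor of E2F target genes, rose by 1.15 ± 0.06. FAS, a death receptor, rose by 0.99 ± 0.07, and SESN2, a stress-inducible regulator of mTORC1, by 1.03 ± 0.06. PLK2 and SESN1, a kinase and a stress-response gene also induced by p53, fell by 0.40 ± 0.05 and by 0.48 ± 0.09. The list was called higher than other genes (camera with a preset inter-gene correlation of 0.01, adjusted p = 7.8e-10 over 27 lists). With an estimated correlation it was not called (adjusted p = 0.20).

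**Figure D3:**
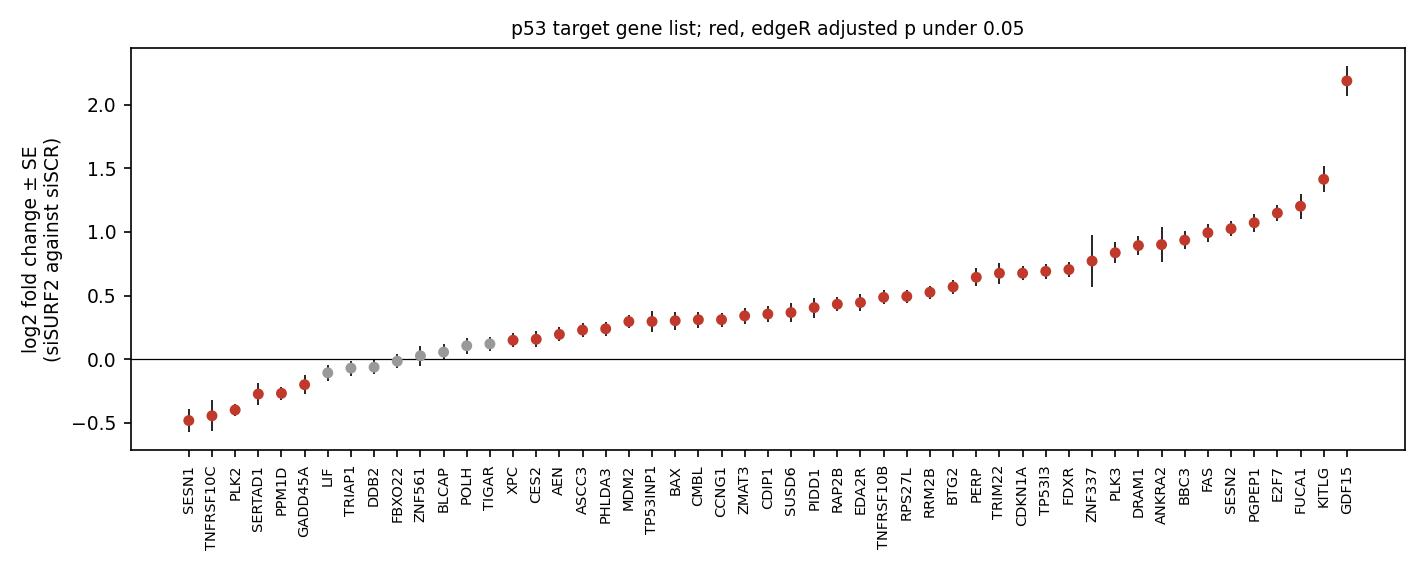
Log2 fold change ± SE (siSURF2 against siSCR, 3 libraries each) of the 51 measured genes of the p53 target list, ordered by value, in red where the edgeR adjusted p was under 0.05. The points run from SESN1 at -0.48 to GDF15 at 2.19, with 37 red points above 0 and 6 below.

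Most measured genes of DNA replication, mitosis and ribosome assembly fell, although none of these lists was called with an estimated correlation. Of 53 measured G1/S and DNA replication genes, 43 fell, 1 rose and 9 did not pass the threshold (44 and 1 when adjusted over the list alone). UNG, which removes uracil from DNA, fell from 100.7 ± 1.04 to 46.6 ± 3.72 CPM (-1.11 ± 0.06), and MCM6, a subunit of the replicative helicase, fell by 0.93 ± 0.05. FANCI, of the Fanconi anaemia pathway, was the member that rose (0.13 ± 0.05, adjusted p = 0.048), and its adjusted p was 0.21 without siSCR replicate 2 and 0.052 with RLE factors, within a range up to 0.92 over all settings tried. The list had a median of -0.38 and was called lower (adjusted p = 4.8e-13), but with an estimated correlation the adjusted p was 0.20. Of 57 G2/M and mitosis genes, 42 fell and 3 rose (44 and 3 when adjusted over the list alone). MAD2L1, of the spindle checkpoint, fell by 0.97 ± 0.05 and CDC20, an activator of the anaphase-promoting complex, by 0.69 ± 0.06, while the kinesins KIF20B and KIF14 rose by 0.46 ± 0.07 and 0.30 ± 0.06. The mitosis list was called lower (adjusted p = 5.4e-06), but with an estimated correlation the adjusted p was 0.32.

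Of 105 ribosome biogenesis factors, 88 fell, 3 rose and 14 did not pass the threshold (89 and 3 when adjusted over the list alone). NMD3, the export adaptor of the large subunit, fell from 82.3 ± 0.174 to 43.6 ± 3.47 CPM (-0.92 ± 0.06), and TSR1, a small-subunit assembly factor, fell by 0.77 ± 0.05. DHX37 and NOP53 rose by 0.28 ± 0.06 and 0.26 ± 0.05. The list median was -0.31 and the list was called lower (adjusted p = 2.1e-11). With an estimated correlation the adjusted p was 0.40. The 79 cytosolic ribosomal protein genes went both ways: 23 rose, 4 fell and 52 did not pass the threshold (21 and 4 when adjusted over the list alone), and the list was not called (adjusted p = 0.44). RPS19 rose by 0.37 ± 0.05 and RPL7 fell by 0.64 ± 0.05, and ribosomal protein counts are uncertain because the genes have many processed pseudogenes. Of 36 genes of the RNA polymerase I and III machinery, 14 fell and 2 rose, POLR3B falling by 0.87 ± 0.09, and the list was not called (adjusted p = 0.086). Of 22 snoRNA host genes, 11 rose and none fell. SNHG29 rose by 0.58 ± 0.05 and ZFAS1 by 0.59 ± 0.06. The list was called higher (adjusted p = 0.010), but with an estimated correlation the adjusted p was 0.59. It was 0.090 with library sizes set by ERCC spike-in totals and 0.062 without both libraries numbered 3, settings chosen after seeing the data.

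Cholesterol synthesis genes fell: 19 of 24 measured members were lower, 2 were higher and 3 did not pass the threshold, and the median was -0.54. HMGCS1, which makes the precursor of mevalonate, fell from 463.1 ± 18.9 to 202.0 ± 2.21 CPM (-1.20 ± 0.05). SREBF2, the transcription factor of the pathway, rose by 0.27 ± 0.05. The list was called lower (adjusted p = 7.2e-11), but with an estimated correlation the adjusted p was 0.25. Of 23 YAP and TEAD target genes, 16 fell and 6 rose, with a median of -0.33 (adjusted p = 3.2e-05). With an estimated correlation the adjusted p was 0.25. CCN1, a matricellular protein, fell from 602.9 ± 32.5 to 256.7 ± 7.79 CPM (-1.23 ± 0.05), and TEAD1, a transcription factor of the pathway, fell by 1.20 ± 0.05. MYOF rose by 0.61 ± 0.05. Of 42 lysosome and autophagy genes, 23 rose and 4 fell, with CTSB, a lysosomal protease, rising by 0.63 ± 0.05 and SQSTM1, an autophagy receptor, falling by 0.42 ± 0.05. The lysosome list was called higher (adjusted p = 0.0025), but with an estimated correlation the adjusted p was 0.20, and it was 0.090 with library sizes set by spike-in totals. The estimate for this list was 0.0050, below the preset 0.01, so a larger correlation was not the source of the change to 0.20.

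Of 24 measured replication-dependent histone genes, 12 rose, 1 fell and 11 did not pass the threshold (13 and 1 when adjusted over the list alone). H2BC5 rose from 24.3 ± 2.72 to 38.6 ± 3.17 CPM (0.67 ± 0.08), and H2AC6 fell by 0.19 ± 0.07 (adjusted p = 0.022). The H2AC6 adjusted p was 0.086 with upper-quartile factors, 0.75 with ERCC scaling (log2 fold change -0.21), and 0.18, 0.15 and 0.077 without siSCR replicate 1, siSURF2 replicate 1 and siSURF2 replicate 2. Its log2 fold change was -0.10, -0.15 and -0.17 without these libraries, in the same order. Most mRNAs of these genes carry no polyA tail, and the genes are near-identical copies, so their counts are uncertain. The list was called higher (adjusted p = 0.032), but with an estimated correlation the adjusted p was 0.58. It was 0.084 without siSCR replicate 2, 0.052 without siSURF2 replicate 3 and 0.073 without both libraries numbered 3.

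**Figure D4:**
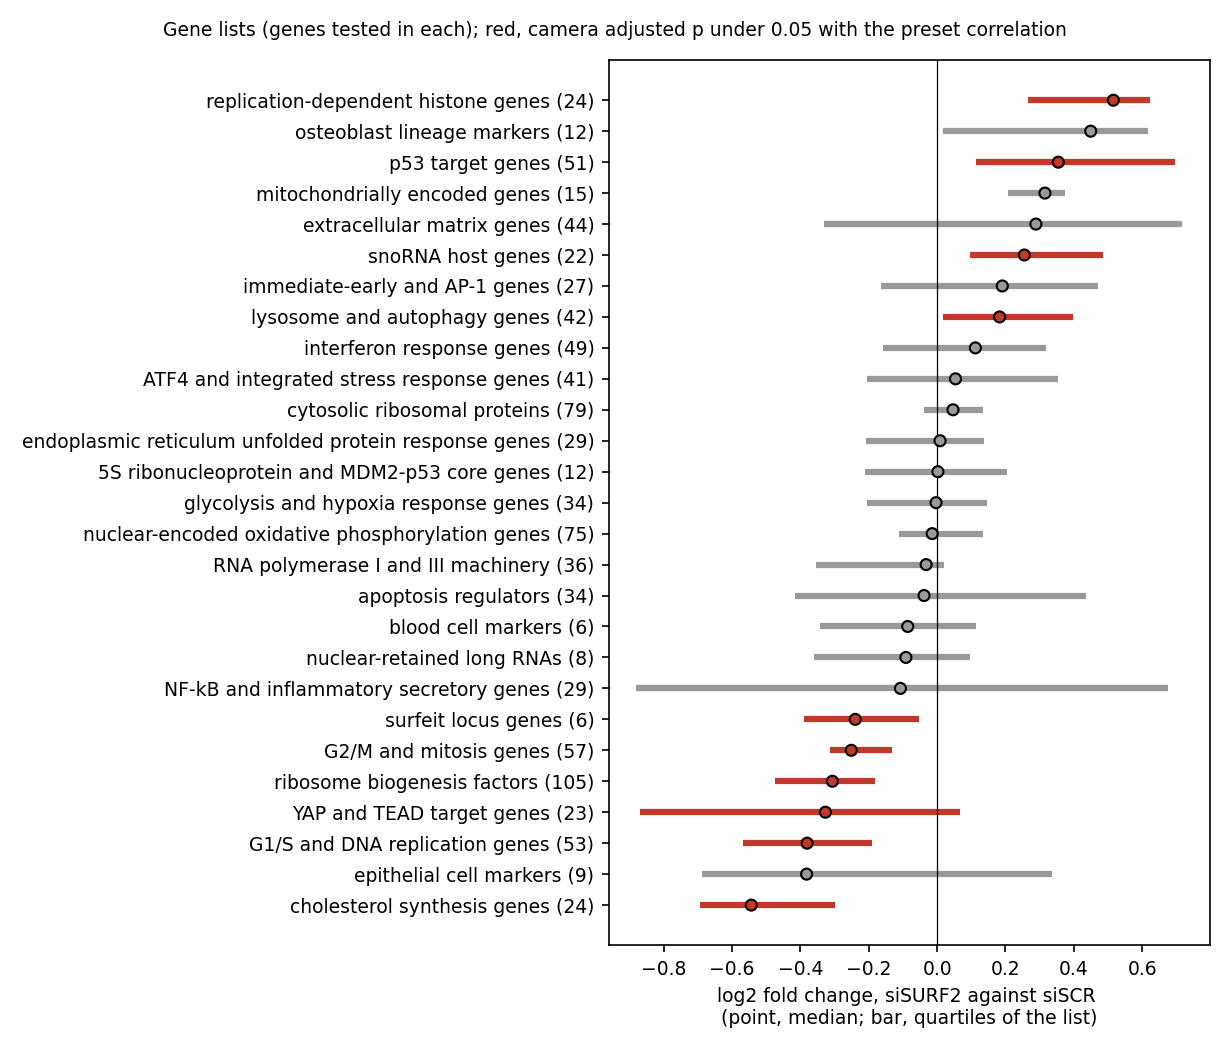
Median log2 fold change (siSURF2 against siSCR, 3 libraries each) of each of the 27 gene lists, with a bar from the lower to the upper quartile of its members and the number of genes tested in brackets. The 10 lists in red passed an adjusted p of 0.05 with the preset correlation, and none of the 27 did with an estimated correlation.

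Several lists had members that moved strongly in both directions and were not called. Over all genes tested, 25.8% rose and 26.2% fell. Of 44 extracellular matrix genes, 22 rose and 14 fell (adjusted p = 0.24). TNC, an adhesion-modulating matrix protein, rose from 43.1 ± 2.48 to 183.9 ± 14.7 CPM (2.09 ± 0.06) and COL5A1, a fibrillar collagen chain, rose by 1.52 ± 0.06, while EFEMP2, an elastic fibre protein, fell by 2.03 ± 0.07. Of 29 NF-kB and inflammatory secretory genes, 10 rose and 13 fell (12 and 14 when adjusted over the list alone, adjusted p = 0.32), with TNFAIP2 rising by 1.27 ± 0.08 and BIRC3, an inhibitor of apoptosis, falling by 1.13 ± 0.06. Of 41 ATF4 and integrated stress response genes, 15 rose and 13 fell (15 and 14 adjusted over the list alone, adjusted p = 0.28). DDIT4, an inhibitor of mTORC1, rose by 2.00 ± 0.11, and SLC7A5, an amino acid transporter, fell by 0.67 ± 0.05. Of 49 interferon response genes, 16 rose and 12 fell (adjusted p = 0.14), NLRC5 rising by 1.27 ± 0.09 and IFIT3 falling by 0.71 ± 0.08. Of 27 immediate-early and AP-1 genes, 15 rose and 7 fell (adjusted p = 0.24), PHLDA1 rising by 2.10 ± 0.09 and HBEGF, a growth factor, falling by 1.86 ± 0.12. Of 34 apoptosis regulators, 14 rose and 14 fell (adjusted p = 0.86). PMAIP1, which encodes NOXA, rose by 1.05 ± 0.05 and BCL2L2, which opposes apoptosis, fell by 0.64 ± 0.06.

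Metabolic and secretory pathway lists were mixed as well. Where their counts lie near the shares over all genes tested (25.8% higher, 26.2% lower), they show no trait of the list. Of 34 glycolysis and hypoxia response genes, 10 rose and 9 fell (adjusted p = 0.98), PFKL rising by 0.80 ± 0.05 and SLC2A3, a glucose transporter, falling by 1.09 ± 0.07. Of 75 nuclear-encoded oxidative phosphorylation genes, 19 rose and 18 fell (adjusted p = 0.98). NDUFA1 rose by 0.63 ± 0.06 and ATP5F1C fell by 0.97 ± 0.05. Of 29 unfolded protein response genes of the endoplasmic reticulum, 8 rose and 10 fell (adjusted p = 0.86), EDEM1 rising by 0.76 ± 0.06 and the chaperone CALR falling by 0.33 ± 0.05. The median, the mean and the list test differed in sign for 3 of the 27 lists: glycolysis, apoptosis and the 5S and MDM2-p53 core genes. For each of the 27 lists without separate numbers, those adjusted over the list alone equalled those over all genes tested.

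Markers of cell identity and of RNA quality were measured in the same way. Of 12 osteoblast lineage markers, 6 rose and 2 fell (adjusted p = 0.086, and 0.037 without siSURF2 replicate 3). PRRX1, a mesenchymal transcription factor, rose by 1.17 ± 0.14, and ALPL, alkaline phosphatase, fell from 3.15 ± 0.132 to 0.742 ± 0.148 CPM (-2.07 ± 0.25). Of 9 measured epithelial markers, 3 rose and 3 fell (3 and 4 adjusted over the list alone, adjusted p = 0.59), CLDN4 rising by 1.07 ± 0.08 and KRT18 falling by 0.69 ± 0.05, with keratin counts uncertain because of pseudogenes. Of 6 measured blood cell markers, 1 fell (PECAM1, -1.34 ± 0.31, at 1.68 CPM in siSCR) and none rose (adjusted p = 0.73). Of 8 long RNAs on a list meant for nuclear-retained ones, 1 rose and 3 fell (adjusted p = 0.38). NORAD, which fell by 0.54 ± 0.05, is mainly cytoplasmic and so no marker of nuclear RNA. None of 15 mitochondrially encoded genes passed the threshold by edgeR, and their median was 0.32 (camera adjusted p = 0.24). MT-RNR2, a mitochondrial ribosomal RNA, was at 0.44 ± 0.19 (adjusted p = 0.13). Its adjusted p was 0.047 with DESeq2, 0.0016 with limma-voom, 9.7e-04 with a non-robust prior and 1.6e-09 without siSURF2 replicate 2. They held 4.68% and 4.72% of the counts in siSURF2 replicates 1 and 3, 2.71% in siSURF2 replicate 2, and 2.89% to 3.49% in siSCR. Over all settings tried, the median of the mitochondrially encoded list ran from 0.13 to 0.51. Its camera adjusted p reached 0.54 on leaving out 1 library. Without siSURF2 replicate 2 the list was called higher with the preset correlation (adjusted p = 1.8e-08, median 0.51). That p is too small for this list, whose estimated correlation over all libraries was 0.96, with an adjusted p of 0.855 from it. That library differed from siSURF2 replicates 1 and 3 by a chi-square per degree of freedom of 8.87 and 10.3, against 2.87 between those 2 libraries.

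Across 17561 genes tested, 4535 were higher and 4596 lower with siSURF2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold change was seen in 820 of the higher and 670 of the lower genes. Among protein-coding genes with the largest changes, AKR1C1, a steroid-metabolising reductase, rose from 0.406 ± 0.223 to 10.9 ± 2.03 CPM (log2 fold change 4.75 ± 0.25, SD and SE over n = 3 each), although reads shared with other AKR1C genes make its level uncertain. PTPN22, a tyrosine phosphatase, rose by 4.51 ± 0.32, HAS2, a hyaluronan synthase, by 3.96 ± 0.30, and GOLGA7B by 3.98 ± 0.21. FCER2, a low-affinity IgE receptor, rose by 3.68 ± 0.26, the chemokine CXCL8 by 3.50 ± 0.27, the matrix protease MMP3 by 3.45 ± 0.21 and RCAN2, a regulator of calcineurin, by 3.37 ± 0.18. TNNT2, cardiac troponin T, fell from 64.0 ± 1.68 to 0.937 ± 0.217 CPM, a 67.8-fold lower level (-6.08 ± 0.12, adjusted p = 8.2e-25). TNNC1, troponin C (-4.28 ± 0.18), and SAA1, an acute-phase protein (-5.26 ± 0.16), also fell, SAA1 having a close paralog that makes its counts uncertain. OLR1, a scavenger receptor (-5.47 ± 0.29), MC5R, a melanocortin receptor (-5.42 ± 0.29), and C4BPB, a regulator of complement (-5.20 ± 0.33), fell as well, as did NLRP10 (-4.40 ± 0.29) and MOB3B (-4.24 ± 0.17). OLR1, MC5R, C4BPB and NLRP10 had between 1 and 6 counts in each siSURF2 library. Of all genes tested, 5030 had every siSURF2 library above every siSCR library and 5029 had the reverse, where chance gives 10% in all. With library sizes set by ERCC spike-in totals, 802 genes were higher and 825 lower, and 50 of 114 named genes lost their call. SURF2 stayed past the threshold under that scaling, while MDM2, CDKN1A, SURF4 and SURF6 had adjusted p-values of 0.68, 0.10, 0.36 and 0.41. Their log2 fold changes were then 0.26, 0.65, -0.44 and -0.42, so the calls ended mainly because the spread within groups widened. Over the 50 genes the log2 fold change shifted by -0.069 to -0.015.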

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

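ERCC scaling, leaving out both libraries numbered 3, and lists without SURF2 or without genes whose 3′ UTR holds AGATGGA or GTGAAGT were chosen after seeing the data. In all other settings the 4 counts of genes stayed within 1.5 times the main count. The balance of higher and lower genes moved with the scaling, to 5154 and 3986 with upper-quartile factors and to 4888 and 4239 with library totals only. The SURF2 log2 fold change stayed past the threshold in all 18 settings, at -3.42 to -3.25. With ERCC scaling, 802 genes were higher and 825 lower, and 50 of 114 named genes lost their call, although their log2 fold changes shifted only by -0.069 to -0.015. The mean ERCC level of the groups differed by 0.038 (log2). The ERCC level of the libraries numbered 3 lay -0.46 (log2) from that of the others, which widens the spread within groups. Of the 9131 main calls, 8774 were kept with library totals only and 7810 to 8218 on leaving out 1 library. The p53 list was called in every setting except the estimated correlation (adjusted p = 0.20, median 0.355, range of adjusted p 2.3e-18 to 0.20). For 9 of the 10 called lists that setting gave the highest adjusted p, the exception being the surfeit list, at 0.50 without genes holding the 7-mers. SURF2 holds GTGAAGT in its own 3′ UTR, so leaving out these genes removes the siRNA target too. Without SURF2 alone the surfeit list was at 0.32. Without a filter 5 more lists passed. Without both libraries numbered 3, 3 of these 5 passed (interferon, extracellular matrix and osteoblast), and the snoRNA host and histone lists were lost. A non-robust prior was not run for lists. In TMM-normalised gene levels, replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.01, -0.13 and -0.02). With the number as a block 4478 genes were higher and 4550 lower. In ERCC level both libraries numbered 3 lay below the mean of all libraries (log2 -0.34 in siSCR and -0.27 in siSURF2). TMM-normalised levels cannot show such a shared shift, and ERCC scaling was not run with the block. Levels under 1 CPM, such as OLR1 in siSURF2, are limited by depth.

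The following reversed without passing the threshold in either setting, and the cause was not tested. For genes the sign of the log2 fold change turned. For lists the direction of the camera test turned, and the median given beside it may keep its sign. The main medians were -0.015 for oxidative phosphorylation (camera down), and -0.0032 for glycolysis, -0.038 for apoptosis and 0.0085 for the unfolded protein response (camera up). The 5S core list was at 0.0022 (camera down). With upper-quartile factors RPL11, MED22 and RPL7A had log2 fold changes of 0.038, 0.023 and 0.0067, and the oxidative phosphorylation list a median of 0.032. With library totals only, RPL11 was at 0.017, MED22 at 0.0033 and that list at 0.011, and without a filter RPL11 was at 0.011 and the list at 0.0049. The list was at -0.010 with the stricter filter, at -0.016 with the replicate block and at -0.013 with members of 1 list only, where the apoptosis list was at -0.089 and the 5S core list at 0.013. On leaving out a library, RPL11 ranged from -0.026 to 0.0056, MED22 from -0.060 to 0.021, RPL7A from -0.083 to 0.0099, the oxidative phosphorylation list from -0.022 to 0.0099 and the glycolysis list from -0.035 to 0.021. With ERCC scaling the unfolded protein list was at -0.049 and the glycolysis list at -0.050. Without both libraries numbered 3, MED22 was at 0.0084 and the oxidative phosphorylation list at 0.0025. The 5S core list was at 0.013 without SURF2 and at 0.0022 without genes holding the 7-mers, SURF2 among them.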

Other observations

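All list and search tests in this part were chosen after the results were seen, except the matched lists for the p53 targets and the genes around SURF2. After AKR1C1 had been seen among the most raised genes, a list of 25 target genes of NRF2, the transcription factor of the antioxidant response, was drawn up, so its direction is not independent evidence. Of its 25 measured members 18 rose, 2 fell and 5 did not pass the threshold (18 and 3 when adjusted over the list alone). NQO1, a quinone reductase, rose by 1.13 ± 0.05 (log2 fold change ± SE), SLC7A11, the cystine transporter, by 0.99 ± 0.06, HMOX1, haem oxygenase, by 0.88 ± 0.06 and FTH1, ferritin heavy chain, by 0.88 ± 0.05. PIR and SRXN1 fell by 0.24 ± 0.07 and 0.25 ± 0.07, and TXNRD1 and GCLM did not pass. The median was 0.48 (camera adjusted p = 3.7e-10 over 28 lists), and with an estimated correlation the adjusted p was 0.25. Under ERCC scaling 9 rose and the median was 0.45. HMGA2, an architectural chromatin protein of embryonic tissue and also named after its values were seen, had the smallest adjusted p among raised genes (1.1e-23) and rose from 64.7 ± 2.42 to 378.2 ± 18.5 CPM (SD, n = 3 each).

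Higher p53 target genes may have a technical source. GC content, length and expression were weighed with 10000 lists matched on them: 0 of the 10000 had a median as high as 0.35, and the highest was 0.17. Genes on a list are co-regulated, so this compares levels and is no replicate test. That the rise belongs to the siRNA used and not to SURF2 stays open, since 1 siRNA label stands against 1 control.

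A second pattern is that mRNAs with certain 7-mers in the 3′ UTR were lower. Of 16251 7-mers searched in 12858 genes, AGATGGA (2416 genes, z = -5.73) and GTGAAGT (z = -5.15) were the lowest, and none of 100 permutations gave a lower value, their lowest being -4.90. Both occur once in the SURF2 mRNA, AGATGGA at 454 to 460 in the coding sequence of exon 4 (chromosome 9, 133360025 to 133360031) and GTGAAGT at 827 to 833 in the 3′ UTR of exon 6 (133361154 to 133361160), while 4.80% of all 7-mers do. A candidate explanation is repression through the seed of an siRNA against SURF2, whose sites would match the target mRNA: genes with at least 2 copies of these 7-mers (1001 genes) lay -0.034 ± 0.020 (log2, mean ± SE) from genes with 1 copy (2427 genes, one-sided permutation p = 0.049). This is close to the threshold, and base composition could give it as well. Both 7-mers were picked on the same fold changes, and a gene with 1 copy of each was counted as having 2. The permutation p is therefore not independent evidence for a seed effect. Base composition stays open as a source. AGATGGA lay -0.83 from the lowest permutation, and the other 139 7-mers of its bases had a median z of -0.81 (bootstrap SD 0.12), not above that gap by more than its spread. The lowest z of those 139 was -3.994. CAGATGG, which overlaps AGATGGA in the SURF2 mRNA, had a z of -4.73. AGATGGG and ACAGATG, which the SURF2 mRNA lacks, lay nearly as low, at -4.64 and -4.38. Of the 20 lowest 7-mers, 5 occur in the SURF2 mRNA. GTGAAGT lay -0.25 from the lowest permutation, and the other 209 7-mers of its bases had a median z of -0.65 and a lowest of -4.395. The siRNA sequence is not given in the sources used here. As the direct cause of all genes at least 2-fold lower, such sites were present in 37.1% of those searched (130 of 350), against 1280 of 5111 genes not past the threshold, so most held none, and indirect effects stay open.

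SURF4 and SURF6 fell with SURF2. Reads of SURF2 counted to SURF4 could also lower SURF4. In the coordinates used here the genes do not overlap, SURF2 ending at 133361169 and SURF4 starting at 133361449. SURF4 lost 75.5 ± 9.60 CPM (SE), more than the 34.8 CPM counted to SURF2 in siSCR. Reads of SURF2 counted to SURF4 would not be among those 34.8 CPM, so this comparison sets no limit on them. SURF2 reads as a source of the SURF4 loss stay open, since the annotation used for counting is not given in the sources used here. A local fall of genes around SURF2 would lower the neighbours, yet the median log2 fold change of 21 other genes within 500 kb was -0.039 (bootstrap SD 0.14), with 3 higher and 5 lower. SURF6 lay at percentile 36.5 of 104 other ribosome biogenesis factors, consistent with it falling as they did. SURF6 also holds GTGAAGT in its 3′ UTR and SURF4 holds neither site, so a seed effect stays open for SURF6.

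The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4535 higher, 4596 lower, 820 at least 2-fold higher and 670 at least 2-fold lower genes, and the highest other split gave 0 of each (edgeR), with 77 to 289 genes at an unadjusted p under 0.05, and 0 by DESeq2 and by limma-voom. In each case 1 of the 10 splits gave as many. The absolute median of the p53 list was 0.35, and 0.16 in the highest other split, so 1 of 10 was as large. The preset camera test gave the p53 list an unadjusted p of 1.2e-10 in the real split and of 2.5e-06 to 0.012 in the 9 others, so a p under 0.05 from it does not set the real split apart. For the number of lists called by camera with the preset correlation, 4 of the 10 splits gave 10 or more, and the highest other gave 11 against 10 in the real split. Every other split keeps 2 libraries of a group together against 1, so it carries part of the group difference. The same split also puts both groups into each set of 3, which widens the spread within sets and holds gene calls down. The 0 genes called in the other splits therefore do not measure how many calls chance alone would give.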
